A study of Mus musculus with 11 samples.

How the data were processed

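Gene expression was measured by bulk RNA sequencing of sorted mouse cells, with RNA isolated with a PicoPure kit and libraries made with a Watchmaker Genomics mRNA kit, per the labels' protocols. The values analysed were whole-number counts per gene in 2 tables the authors deposited, 1 with the 8 lung libraries and 1 with all 11 libraries, each with 57186 gene entries. The lung columns held identical counts in both tables, with 0 differing columns. The submitters' processing notes name the GRCm39 build and DESeq2. The aligner, the counting program, the gene annotation and whether counting used the strand are not given in the sources used here. Ensembl gene identifiers and symbols were taken as deposited, where 535 entries had no symbol and 235 symbols stood on more than 1 entry. The annotation at hand was of another build (GRCm38), so no coordinates are given, and the RefSeq gene table of assembly GRCm38.p6 served only for which genes neighbour each other.

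Samples were grouped by the labels as ZsGreen-negative lung ILC2 (n = 5), ZsGreen-positive lung ILC2 (n = 3) and thymic DN3 cells (n = 3). Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. Sex-linked transcripts, given at the end, place DN3 library 1 in other animals than DN3 libraries 2 and 3, so the DN3 spread is not only technical. No replicate pair agreed within sampling noise: chi-square per degree of freedom lay between 1.77 and 15.3 over 16 pairs compared. The labels give a date as batch: 2 September 2024 for ZsGreen-negative libraries 1 to 4 and ZsGreen-positive libraries 1 and 2, 8 April 2025 for ZsGreen-negative library 5 and ZsGreen-positive library 3, and 17 October 2024 for all DN3 libraries. Tissue and batch therefore cannot be told apart in any comparison with DN3.

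The designs, gene lists, rule for named genes and alternatives, apart from 5 alternatives added later (the structural score as a term for genes, lists and DN3 sets, a single ZsGreen-positive library, and DN3 sets without genes of other cells), were fixed before the data were examined. Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust dispersions, filterByExpr by group with a minimum count of 10), with Benjamini-Hochberg (BH) adjustment and a threshold of 0.05. The lung comparison used the 8 lung libraries with batch as a term and tested 13771 genes. DN3 were compared with each lung group, and with all lung ILC2 weighted by library number, in a fit of all 11 libraries without a batch term, which tested 15132 genes. Levels are CPM, counts relative to the library total, after TMM scaling, within the lung libraries for the lung comparison and over all 11 libraries for DN3, so a gene's lung level differs slightly between them. Log2 fold changes are given with standard errors (SE), and levels with standard deviations (SD).

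The 30 gene lists covered the CD3 complex and proximal T cell receptor (TCR) signalling, TCR gene segments, pre-TCR and V(D)J recombination, Notch and T lineage commitment, early thymic progenitors, ILC2 identity, ILC2 cytokines and effectors, ILC progenitors, ILC3 and type 17 genes, ILC1, NK and cytotoxic genes, alpha-beta T cells, gamma-delta T cells, cell cycle, fetal and imprinted genes, immediate early genes, interferon response, tissue residency, co-stimulation, cytokine receptors, neuro-immune receptors, MHC class II, lipid storage, glycolysis, B cells, macrophages, neutrophils and mast cells, lung structural cells, erythroid and platelet transcripts, mitochondrial transcripts and ribosomal proteins. Lists with 3 or more tested genes (29 in each fit) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with BH adjustment over the lists, and again with an estimated correlation. Camera compares a list with the other genes; fry, run as well, tests a list against no change, so its counts answer another question. The 200 genes of smallest p that were at least 2 log2 units higher in DN3 than in all lung ILC2, and the 200 likewise lower, formed DN3-high and DN3-low sets. The weights of that contrast make it uncorrelated with the difference between the lung groups. A library's position was its mean log2(CPM + 1) over the DN3-high set minus that over the DN3-low set.

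Named genes were, per direction in the lung comparison, the 12 called genes of smallest p with at least 5 CPM in the higher group. In DN3 against all lung ILC2 they were the 12 of largest fold change with at least 50 CPM in the higher group and no overlap between DN3 and lung libraries. Up to 4 members of smallest p per list and a fixed set of lymphocyte genes were added. Unnamed gene models, ribosomal, mitochondrial, pseudogene, Xist and Y-linked entries were counted but not named, apart from a look at Xist and Ddx3y chosen after the data were seen. A few genes that the rule takes are not reported here. For a gene at 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval. Floors and intervals cover counting error only.

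A lung structural score, added after the data were seen, was the mean log2(CPM + 1) of 28 structural-cell markers under 1 CPM in DN3. Alternatives comprised 2 other scalings, other filters, DESeq2 1.42.0, limma voom, a fold limit, batch left out or replaced by a surrogate variable (sva 3.50.0), the 2024 batch alone, the replicate number as a block, each library left out, and the score as a term. The tests were tried on simulated counts with known changes, drawn with 1 dispersion of 0.02 for every gene, and the shares recovered hold for that setting. For the lung comparison (13492 genes), 16.7%, 89.2% and 100% of genes changed by 0.5, 1 and 2 log2 units were recovered, with 5 false calls among 138. For DN3 against all lung ILC2 (14460 genes), these shares were 34.3%, 89.4% and 100%, with 12 false calls among 159.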

Results

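Group 2 innate lymphoid cells (ILC2), tissue lymphocytes that secrete type 2 cytokines, were sorted from the lungs of 14-day-old mice, and DN3 cells, T cell precursors at the stage of TCR beta rearrangement, from the thymus. The mice carried Cre recombinase under the control of Cd3g and a Rosa26 reporter in which Cre removes a stop sequence ahead of ZsGreen, so a ZsGreen-positive cell is one that expressed Cd3g itself or descends from a cell that did. Counts per gene were obtained for 5 libraries of ZsGreen-negative ILC2, 3 of ZsGreen-positive ILC2 and 3 of DN3. Total counts ranged from 4495260 to 14424313 in ZsGreen-negative, from 5762491 to 17627469 in ZsGreen-positive and from 5951494 to 7745062 in DN3 libraries. A single count thus stood for 0.0567 to 0.222 CPM.

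The first comparison set ZsGreen-positive against ZsGreen-negative lung ILC2. Cd3g was read in every ZsGreen-negative library, at 122 to 453 counts, so ZsGreen-negative does not mean free of Cd3g RNA. ZsGreen-positive ILC2 held more RNA of the CD3 complex, the signalling part of the T cell receptor. Cd3g (ENSMUSG00000002033) rose 4.34-fold, from 32.8 ± 3.91 CPM (SD, n = 5) to 142 ± 15.3 CPM (SD, n = 3), and Cd3e (ENSMUSG00000032093) rose 14.5-fold, from 1.49 ± 0.521 to 21.4 ± 3.79 CPM. Cd247, which encodes the zeta chain, rose 2.73-fold, from 8.74 ± 1.31 to 23.9 ± 2.70 CPM. Cd3d stayed low, at 0.507 ± 0.165 and 2.19 ± 0.572 CPM.

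The log2 fold changes were 2.12 ± 0.10 for Cd3g (SE; edgeR quasi-likelihood, BH-adjusted p = 9.76e-10), 3.86 ± 0.24 for Cd3e (edgeR BH-adjusted p = 3.26e-08), 1.45 ± 0.16 for Cd247 (edgeR BH-adjusted p = 2.17e-05) and 2.01 ± 0.45 for Cd3d (edgeR BH-adjusted p = 0.0128). Each of these genes was higher in all 3 ZsGreen-positive than in all 5 ZsGreen-negative libraries. The Cd3d call was lost without ZsGreen-negative library 5 (edgeR BH-adjusted p = 0.0654), ZsGreen-positive library 2 (0.106) or ZsGreen-positive library 3 (0.115), and its adjusted p ranged from 0.000261 to 0.761 over 22 alternatives. In the list of CD3 and proximal TCR signalling genes, 7 of 19 tested genes rose and 0 fell, against 11 and 1 adjusted over the list alone. The list was higher as a set (camera, BH-adjusted p = 2.03e-16), also with an estimated correlation (adjusted p = 0.00677). It holds Cd3g, on which the reporter depends, and Cd3e, Cd3d and Cd247, and was not tested without them. Its median log2 fold change was 0.30 and its mean 0.61, so the set result is no separate evidence for TCR signalling genes. Ubash3a, a negative regulator of TCR signalling, was another riser, from 57.9 ± 5.54 to 96.4 ± 9.27 CPM, whereas the kinase gene Lck, chosen after its values were seen, measured 42.7 ± 3.79 and 54.9 ± 10.1 CPM with no call (edgeR BH-adjusted p = 0.0905). Markers of lung structural cells moved with the same libraries, with a list median 1.33 log2 units higher in ZsGreen-positive ILC2.

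**Figure D1:**
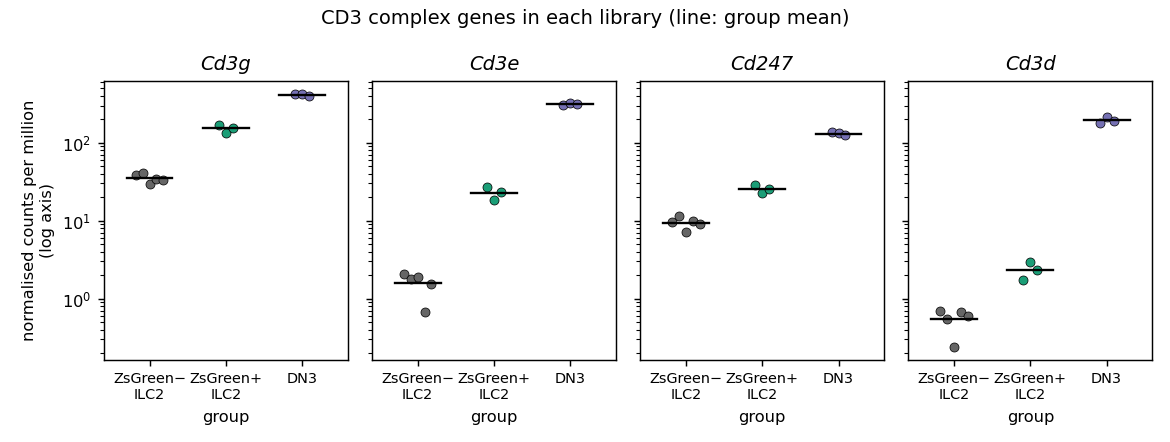
Normalised CPM (log axis) of Cd3g, Cd3e, Cd247 and Cd3d in each of the 11 libraries, by group, with the group mean as a line. ZsGreen-positive ILC2 lie between ZsGreen-negative ILC2 and DN3. For Cd3g the libraries of these groups lie at 29.3 to 40.8 (ZsGreen-negative), 134 to 169 (ZsGreen-positive) and 398 to 426 CPM (DN3). The scale is that of all 11 libraries before filtering, so values differ slightly from those in the text.

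Other genes of smallest p that rose in ZsGreen-positive ILC2 were of several kinds. Klrg1, an inhibitory lectin-like receptor of activated ILC2, rose from 118.9 ± 16.4 to 266 ± 6.96 CPM, and Scart1, a scavenger receptor family member known from gamma-delta T cells, from 5.56 ± 1.22 to 44.8 ± 14.0 CPM. The actin regulator Enah rose from 17.8 ± 2.03 to 51.1 ± 9.05 CPM and the phospholipid-binding annexin Anxa2 from 53.3 ± 5.51 to 110 ± 11.1 CPM. H2-Q7, Plac8, the adhesion molecule L1cam, the dynein gene Dnah8 and the TCR gamma constant gene Trgc4 rose by log2 fold changes of 0.83 to 1.26. H2-Q7, Scart1 and the TCR gamma genes have near-identical copies or relatives, so their counts are uncertain. All of these genes except Plac8, L1cam, Dnah8 and Trgc4 had an edgeR BH-adjusted p of 4.44e-06 or lower.

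Genes of smallest p that fell in ZsGreen-positive ILC2 were likewise of several kinds. Jag1, a Notch ligand, fell from 435 ± 48.9 to 176 ± 34.4 CPM, Hes1, a Notch-induced repressor, from 144 ± 7.22 to 83.7 ± 9.42 CPM, and Bmp2, a bone morphogenetic protein, from 86.4 ± 10.99 to 36.02 ± 3.70 CPM. The transcription factor Sox4 fell from 31.6 ± 4.54 to 10.5 ± 0.551 CPM and the retinoid receptor gene Rxrg from 59.0 ± 3.28 to 24.8 ± 2.51 CPM. The log2 fold change of Jag1 was −1.28 ± 0.10 (SE; edgeR BH-adjusted p = 6.03e-07). Kctd12, Stxbp6, Nyap2, Serpinb2, Mylip and the mast cell carboxypeptidase gene Cpa3 also fell, with log2 fold changes from −2.18 to −0.82. Beside a structural marker median 1.33 log2 units higher in the same libraries, each of the genes named here as falling remained called with the structural score as a term, as did 11 of the 12 highest-ranked risers; L1cam did not (edgeR BH-adjusted p = 0.0809, the highest over 23 alternatives, the lowest being 2.61e-16).

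**Figure D2:**
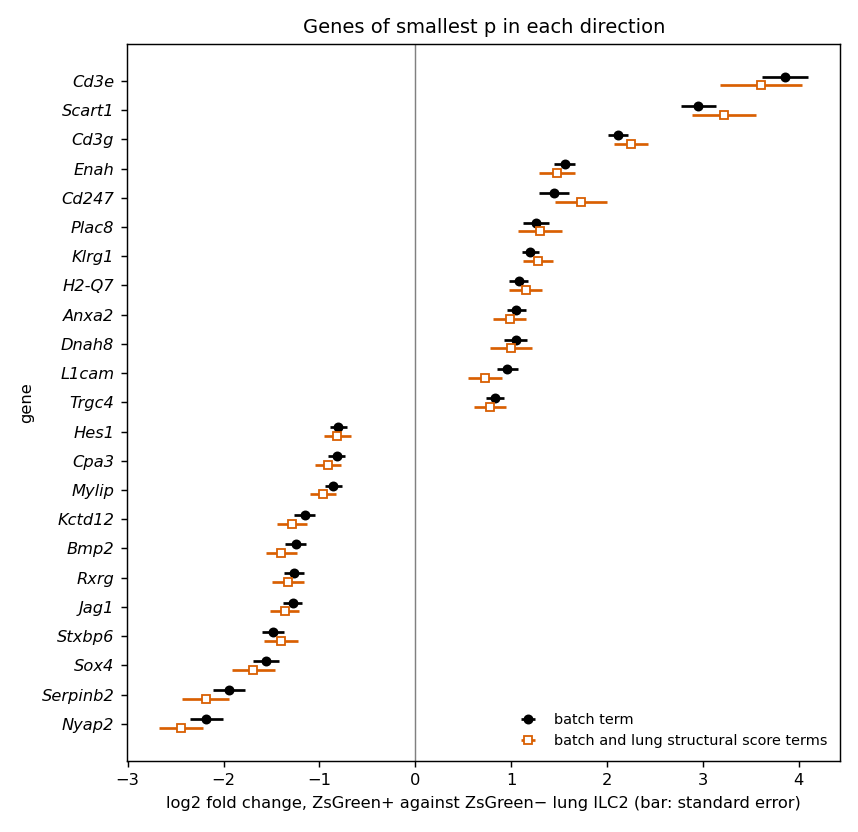
Log2 fold changes between ZsGreen-positive and ZsGreen-negative lung ILC2 with standard errors, for the genes of smallest p in each direction, fitted with batch alone (circles) and with batch and the lung structural score (squares). Every gene shown keeps its direction, from Nyap2 at −2.18 to Cd3e at 3.86 with batch alone.

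ILC2 identity genes moved in both directions. Of 35 tested members, 3 rose and 4 fell, against 5 and 5 adjusted over the list alone, and the list was not called (camera, BH-adjusted p = 0.351). The ILC2 regulators Gata3 (949 ± 114 and 859 ± 88.0 CPM), Rora (1405 ± 247 and 1210 ± 225 CPM) and the IL-33 receptor gene Il1rl1 (2952 ± 291 and 2789 ± 371 CPM) were not called. The co-stimulatory receptor gene Icos fell from 790 ± 121 to 404 ± 34.2 CPM (edgeR BH-adjusted p = 8.35e-05). Among ILC2 cytokines and effectors, 4 of 22 rose and 3 fell, against 9 and 4 adjusted over the list alone (camera, BH-adjusted p = 0.104 for the list). Il13 rose from 596 to 989 CPM (log2 fold change 0.79 ± 0.12, SE) and Il4 from 12.1 ± 2.87 to 27.6 ± 4.70 CPM, while Il5 measured 434 ± 196 and 383 ± 139 CPM with no call. With the structural score as a term, Il13 (edgeR BH-adjusted p = 0.131) and Il4 (0.0528) were no longer called, and Icos was (0.00442). The log2 fold change of Il13 was then 0.73 ± 0.19 (SE), and that of Il4 1.13 ± 0.25 against 1.25 ± 0.15 without the score, so the errors widened more than the changes shrank. Over 23 alternatives the highest adjusted p was 0.442 for Il13, 0.0528 for Il4 and 0.0516 for Icos, and the lowest was 9.38e-16, 1.96e-13 and 3.3e-22. The structural marker median was 1.33 log2 units higher in the same libraries.

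Genes of T cell development gave a mixed picture. TCR gene segments rose in 4 of 25 members (4 adjusted over the list alone), among them Trdc, the TCR delta constant gene, from 3.31 ± 0.734 to 9.48 ± 1.53 CPM. That list was called higher (camera, BH-adjusted p = 0.0348), a call lost at an adjusted p = 0.556 with an estimated correlation. In the gamma-delta T cell list 3 of 10 genes rose and 1 fell, against 5 and 1 adjusted over the list alone, and in the alpha-beta T cell list 4 of 17 rose and 1 fell, against 6 and 3. Neither list was called (camera, BH-adjusted p = 0.0906 and 0.135), and Trac, the TCR alpha constant gene, measured 1.93 ± 0.584 and 2.67 ± 1.65 CPM. In the Notch and T lineage list 1 of 15 rose and 2 fell, against 3 and 2 adjusted over the list alone (camera, BH-adjusted p = 0.647), with Lef1 falling from 31.4 ± 2.70 to 16.9 ± 2.08 CPM and the commitment factors Tcf7 and Bcl11b not called. Of 6 tested pre-TCR and recombination genes, edgeR called 0, adjusted over the list alone also 0, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma voom. Rag2 and Ptcra had 0 counts in all 8 lung libraries, which allows up to 0.0791 CPM in ZsGreen-negative and 0.0976 CPM in ZsGreen-positive ILC2, and Rag1 had 8 and 3 counts. Trdc, Lef1 and Ubash3a were no longer called with the structural score as a term. The log2 fold change of Trdc went from 1.55 ± 0.24 (SE) to 1.07 ± 0.38, while Lef1 stayed at −0.89, with an SE of 0.12 and then 0.20, and Ubash3a at 0.71, with an SE of 0.09 and then 0.16. Structural markers, with their median 1.33 log2 units higher, moved with these groups too.

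Markers of other lung cells were higher in the ZsGreen-positive libraries. Of 32 tested epithelial, endothelial and stromal markers 5 rose, 16 adjusted over the list alone, with a median log2 fold change of 1.33; edgeR's 5 calls stood beside 12 by DESeq2 and 14 by limma voom. Cldn18, an alveolar tight junction gene, rose from 5.53 ± 2.43 to 14.99 ± 3.14 CPM and Cldn5, its endothelial relative, from 5.25 ± 2.05 to 12.1 ± 2.10 CPM. The Cldn5 call was lost without ZsGreen-negative library 5 (edgeR BH-adjusted p = 0.081) or ZsGreen-positive library 3 (0.102), within a range of 3.45e-07 to 0.911 over 23 alternatives. The list was called (camera, BH-adjusted p = 8.6e-14), but not at an adjusted p = 0.556 with an estimated correlation. The structural score was 3.24 ± 0.58 (SD, n = 5) in ZsGreen-negative and 4.39 ± 0.47 (SD, n = 3) in ZsGreen-positive libraries (two-sided exact permutation p = 0.0536), and 0.1 in the exact test within batch. Macrophage and dendritic markers (2 of 15 rose, also 2 adjusted over the list alone), B cell markers (1 of 7, or 3), early thymic progenitor genes (1 of 10, or 3) and MHC class II genes (0 of 10, or 1) were called higher as lists (camera, BH-adjusted p = 0.00141, 0.0348, 0.0348 and 0.0439). These calls were lost, with adjusted p = 0.556, 0.556, 0.556 and 0.661 with an estimated correlation. For the MHC class II genes, edgeR's 0 calls stood beside 4 genes at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma voom. Mitochondrially encoded transcripts were called lower (2 of 13 fell, 4 adjusted over the list alone; camera, BH-adjusted p = 5.39e-05), lost at an adjusted p = 0.556 with an estimated correlation.

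**Figure D3:**
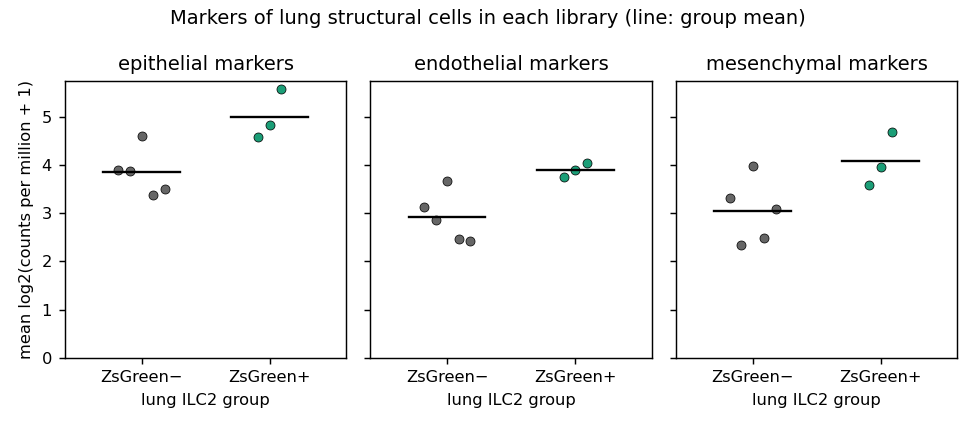
Mean log2(CPM + 1) of epithelial, endothelial and mesenchymal markers in each of the 8 lung libraries, with the group mean as a line. The ZsGreen-positive means are higher in each class, while ZsGreen-negative library 3 reaches the range of the ZsGreen-positive libraries in the epithelial and mesenchymal classes.

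In number, 323 of 13771 tested genes rose and 300 fell in ZsGreen-positive ILC2 (edgeR quasi-likelihood, BH-adjusted p under 0.05), 168 and 64 of them by at least 1 log2 unit. Over all genes tested the groups did not overlap for 10.2%, where chance gives 3.57%. Within the 2024 batch (4 against 2 libraries), 145 rose and 153 fell. In the 2025 batch (1 against 1, so no test), in a check added after the data were seen, 287 of 297 genes called in the 2024 batch alone and measured there had the same direction. The counts were 146 and 140 without ZsGreen-negative library 5, 149 and 172 without ZsGreen-positive library 2 and 148 and 154 without ZsGreen-positive library 3. With the structural score as a term, 17 of the 323 and 48 of the 300 remained called. The median log2 fold change of the 323 went from 1.05 (median SE 0.19) to 0.60 (median SE 0.31), and that of the 300 from −0.58 (median SE 0.12) to −0.61 (median SE 0.18), so the genes that fell kept their size while their errors widened.

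The DN3 comparisons asked where lung ILC2 stand relative to T cell precursors. DN3 expressed genes of antigen receptor assembly that had few or no counts in lung ILC2. Rag1, a subunit of the recombinase, reached 1265 ± 47.5 CPM (SD, n = 3) against 0.205 ± 0.214 CPM (SD, n = 8) in all lung ILC2, and Ptcra, the pre-TCR alpha chain, 139 ± 6.15 CPM against 0 counts, or at least 2977-fold higher. Dntt, the terminal transferase, had 1080 ± 35.7 CPM in DN3 against 2 counts in all lung libraries, a ratio of 34640 (95% counting interval 9590 to 286100). Lung ILC2 in turn expressed Il1rl1 at 3100 ± 329 CPM and the growth factor gene Areg at 1780 ± 182 CPM, both at 0 counts in DN3, or at least 25780-fold and 14800-fold lower there. The CD3 genes were highest in DN3, with Cd3g at 421 ± 11.1, Cd3e at 322 ± 12.4, Cd3d at 198 ± 17.5 and Cd247 at 133 ± 4.28 CPM.

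Against all lung ILC2, 5551 of 15132 tested genes were higher in DN3 and 6374 lower (edgeR quasi-likelihood, BH-adjusted p under 0.05), 78.8% of those tested. Against ZsGreen-negative ILC2 5369 were higher and 6240 lower, and against ZsGreen-positive ILC2 5267 and 6098. Cd3g was 3.58 log2 units higher in DN3 than in ZsGreen-negative ILC2 and 1.47 higher than in ZsGreen-positive ILC2, and Cd3e 7.66 and 3.80 units higher. Against all lung ILC2 the edgeR BH-adjusted p was 1.36e-18 for Cd3g, 1.08e-21 for Cd3e, 5.42e-23 for Rag1 and 1.23e-20 for Il1rl1, and each of these genes was separated between all 3 DN3 and all 8 lung libraries. DN3 formed a batch of their own, so tissue and batch cannot be told apart. Upper-quartile scaling moved the median of all genes from −0.09 to 0.01 log2 units, a shift of 0.101, against which all changes here are to be read. With that scaling 6014 genes were higher in DN3 and 5938 lower than in all lung ILC2, so the excess of lower genes depends on the scaling. None of the list medians given for DN3 changed sign under the other scalings.

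Other DN3-enriched genes were the solute carriers Slc5a9 (at least 2844-fold higher) and Slc16a5, Rag2 (at least 1544-fold), Fam163b (at least 1391-fold), Arpp21 (446 ± 11.9 against 0.551 ± 0.501 CPM), the granzyme gene Gzma (169 ± 13.6 against 0.186 ± 0.228 CPM), Prss57, Khdc1a and Dgkeos. Dgkeos lies opposite another gene, so its counts are uncertain where strand use is not stated. Pre-TCR and recombination genes were higher in 13 of 15 members and lower in 2, CD3 and TCR signalling genes in 13 and 6 of 20, and Notch and T lineage genes in 11 and 2 of 16 (camera, BH-adjusted p = 6.55e-20, 2.22e-06 and 2.36e-11), calls kept with an estimated correlation. Notch1 stood at 1307 ± 20.8 against 76.4 ± 12.1 CPM and Tcf7 at 1880 ± 60.0 against 36.7 ± 7.07 CPM. All 40 cell cycle genes were higher, Mki67 at 759 ± 20.2 against 191 ± 28.8 CPM, and so were 45 of 58 TCR segments with 2 lower, 13 of 20 alpha-beta T cell genes with 5 lower and 10 of 14 gamma-delta T cell genes with 4 lower (camera, BH-adjusted p = 2.22e-24, 1.31e-10, 0.00113 and 0.000131). These calls were lost, with adjusted p = 0.066, 0.125, 0.191 and 0.191 with an estimated correlation. Adjusted over the list alone, the counts of every list in this paragraph were the same.

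ILC2 genes were lower in DN3. Of 35 ILC2 identity genes 34 were lower and 1 higher, and of 22 cytokines and effectors 21 were lower and 0 higher (camera, BH-adjusted p = 1.8e-35 and 7.95e-24), with list medians of −4.53 and −10.04 log2 units, or −4.53 and −8.48 with genes of few counts at their bound. The ILC regulators Rora (1.90 ± 0.624 against 1428 ± 262 CPM) and Id2 (10.4 ± 0.395 against 630 ± 89.0 CPM) were low in DN3, and Il13, Csf2, Ccl1, Cxcl2 and the chemokine receptor gene Ccr8 had 0 counts there, or at least 6627-fold, 6321-fold, 3542-fold, 12480-fold and 8026-fold lower. Pcsk1, Myadm, Rnf128, Atf3 and Sdc4, also at 0 counts, were at least 2210-fold lower. Immediate early genes (27 of 30 lower, 2 higher), neuro-immune receptors (20 of 20), cytokine receptors (23 of 30, 7 higher) and tissue residency genes (17 of 22, 4 higher) were lower as lists (camera, BH-adjusted p = 2.88e-23, 3.32e-18, 2.93e-12 and 1.2e-09). All 6 lists so far kept their calls with an estimated correlation. The immediate early list also covers genes of the response to cell dissociation, and its members Fosl2, Nr4a1, Dusp1 and Atf3 are in the DN3-low set. Handling of lung and thymus was not told apart from cell identity. Co-stimulatory receptors (17 of 23 lower, 4 higher), ILC progenitor genes (11 of 18, 6 higher), ILC3 and type 17 genes (11 of 16, 5 higher) and lung structural markers (29 of 32, 3 higher) were also called lower (camera, BH-adjusted p = 2.95e-09, 0.0299, 0.0401 and 0.0283), but lost the call, with adjusted p = 0.0552, 0.299, 0.299 and 0.661 with an estimated correlation. Counts adjusted over the list alone were the same, and the structural median was −7.00 log2 units, or −6.05 with genes of few counts at their bound.

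No shift of the DN3-high or DN3-low genes between ZsGreen-positive and ZsGreen-negative ILC2 passed the test. Of the 142 DN3-high genes tested in lung, 12 rose and 9 fell, with a mean log2 fold change of 0.10 (camera p = 0.68, and 0.801 with an estimated correlation), and of the 200 DN3-low genes 26 rose and 20 fell, with a mean of −0.00211 (camera p = 0.964, and 0.983 with an estimated correlation). Over all genes tested in lung 4.52% were called. Of the 323 that rose, 272 were lower and 38 higher in DN3, where independent calls give 148.1 and 106. Of the 300 that fell, 221 were lower and 51 higher, where independent calls give 137.6 and 98.47. Called genes of both directions were thus more often lower in DN3. On the lung ILC2 to DN3 axis ZsGreen-negative libraries lay at −5.32 ± 0.06 (SD, n = 5) and ZsGreen-positive libraries at −5.26 ± 0.08 (SD, n = 3), a difference of 0.05 (two-sided exact permutation p = 0.357, where 0.0179 is the smallest possible). The DN3 mean was 4.58, in libraries that also served to choose the sets. The 50 DN3-high genes of smallest p include Cd3e, Cd3d, Trdc and Trgc2, which rose in ZsGreen-positive ILC2, and Lef1 and Sox4, which fell. No set of 50 genes was tested without the CD3 and TCR genes. A rise of that set is therefore no separate evidence for a wider shift towards DN3. A DN3-high set of 50 genes in place of 200 had a mean of 0.34 log2 units and passed the threshold of 0.05 in camera (p = 0.0292), whereas a set of 500 had a mean of 0.0043 (camera p = 0.465), and with 50 genes in each set the axis difference was 0.126 (exact permutation p = 0.0536), with 500 it was 0.0301 (0.589).

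**Figure D4:**
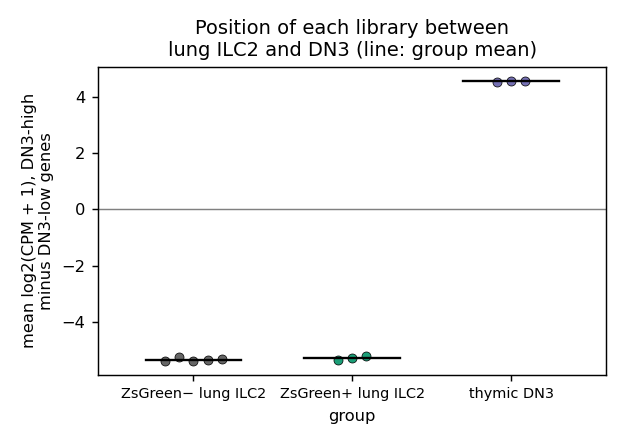
Position of each of the 11 libraries, as mean log2(CPM + 1) over DN3-high genes minus that over DN3-low genes, with the group mean as a line. Lung libraries lie between −5.39 and −5.21 on the scale of all 11 libraries, and DN3 between 4.56 and 4.59.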

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

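Of the tests in this part, only the thinning of libraries to equal depth was set down before its result was seen; the tests of RNA from other lung cells, of the CD3 gene ratio, of the neighbours of the reporter locus and of other splits of the libraries were chosen or written down after the results they bear on had been seen.

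In each of 160 measures, the ZsGreen-negative libraries (n = 5) were searched for a value far from the other 4, taking the gap to the nearest library as a share of the whole range, and 16 exceeded the critical value of 0.71. Chance alone marks about 1 in 20 groups, or 8 of 160, and the measures are not independent. ZsGreen-negative library 5, of the 2025 batch, stood highest in total counts (share 0.775), genes detected (0.887), Tcf7 (0.763) and Zfp36 (0.77), and lowest in Cpa3 (0.798) and Ctla4 (0.855). ZsGreen-negative library 3 stood highest in early thymic progenitor genes (0.772), gamma-delta T cell genes (0.799), Jag1 (0.731), Gata2 (0.915) and Lyz2 (0.756), and lowest in Klrk1 (0.804). ZsGreen-negative library 4 stood highest in interferon response genes (0.812) and Irf9 (0.732) and lowest in Klf3 (0.81), and ZsGreen-negative library 2 highest in the mitochondrial share of counts (0.787).

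Markers of lung structural cells were higher in ZsGreen-positive ILC2, with medians of 1.40, 1.35 and 1.11 log2 units for 12 epithelial, 8 endothelial and 10 mesenchymal genes. Thinning each library to the lowest total of 4495260 counts left a list median of 1.26 against 1.33. Such thinning keeps the expected ratios between libraries, so it could hardly lower the median and does not decide on sequencing depth. The 3 classes moved alike, the lowest at 1.11, so RNA or cells of other lung types in the sorts may be the source of these markers; cells and free RNA were not told apart. For the 323 genes called higher, the structural score as a term took the median log2 fold change from 1.05 (median SE 0.19) to 0.60 (median SE 0.31), and calls ended both because changes shrank and because the score, which differs between the groups, widened the errors. For the 323 as a set, RNA of other lung cells and a difference between the ILC2 groups therefore cannot be told apart, and the latter stays open; 17 of them, Cd3g, Cd3e and Cd247 included, keep their call with the score.

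The rise of Cd3g, Cd3e and Cd247 is not accounted for by RNA of epithelial, endothelial and mesenchymal lung cells as the whole cause, since with their score as a term the smallest of the 3 log2 fold changes was 1.73 ± 0.27 (SE, Cd247; edgeR BH-adjusted p = 0.00254). Cells with the CD3 gene levels of DN3 in the sort are argued against as well: the rise of Cd3d was at most 14.1% of that of Cd3e in a ZsGreen-positive library, against at least 59.3% in each DN3 library. The score does not cover T cells, and T cells with another ratio of CD3 genes were not tested and stay open. A candidate explanation is expression of these genes in the ZsGreen-positive ILC2 themselves, sorted by a reporter of Cd3g expression, which was not tested.

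Gt(ROSA)26Sor, the transcript of the locus that carries the reporter and chosen after its values were seen, fell from 62.5 ± 9.52 CPM (SD, n = 5) to 28.6 ± 1.73 CPM (SD, n = 3), a log2 fold change of −1.07 ± 0.12 (SE; edgeR BH-adjusted p = 3.62e-05). A lower level of the whole region is argued against, since among the 2 tested neighbours on each side, in the gene order of assembly GRCm38.p6, the lowest log2 fold change was −0.26 ± 0.13 (Thumpd3). Gt(ROSA)26Sor lies antisense to Thumpd3, so without stated strand use its counts are uncertain; the call held in 23 alternatives (edgeR BH-adjusted p up to 0.0158). Recombination of the reporter allele may alter this transcript, but in the lung libraries it coincides with the groups by design and was not tested.

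For the 623 genes called between the lung groups, 1 of the 56 splits of the 8 libraries, the real one, gave as many. The highest other split gave 122 and set apart ZsGreen-negative libraries 2, 4 and 5, which have the lowest structural scores. Other splits mix the lung groups and so hold the group difference as spread, and they were not kept within batch. With 1 of 56 the smallest share possible, the count was rare among the splits, but chance is not excluded. For the 8 lists called between the lung groups chance cannot be excluded, with 16 of 56 splits as large and the highest other at 15. These splits count lists and test no single one, and the CD3 and TCR signalling list keeps its camera call with an estimated correlation (adjusted p = 0.00677). That list holds the CD3 genes, Cd3g included, and was not tested without them. Chance cannot be excluded either for the DN3-high set (48 of 56; −log10 p of 0.168, highest other 2.75) and the DN3-low set (55 of 56; 0.0159, highest other 1.95). For DN3 the real split gave the most genes, 11609 against ZsGreen-negative ILC2 (1 of 56, highest other 0). Against all lung ILC2 it gave 11925 (1 of 100 drawn from 165, highest other 1). For its 18 lists, 8 of 100 splits gave as many, with the highest other at 20. The other splits mix DN3 and lung libraries and so carry the DN3 difference themselves, as spread within the groups. Their counts therefore do not decide on chance, for genes or for lists. With an estimated correlation 9 of the 18 lists keep their call. The 10 splits of DN3 and ZsGreen-positive libraries are too few for a share under 0.05, with 11365 genes in the real split (1 of 10) and 0 in the highest other.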

How the results depend on the processing

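The 5 alternatives added after the data were seen were the structural score as a term for genes, for lists and for the DN3 sets, the lung comparison with ZsGreen-positive library 1 as the lone library of its group, and the axis position without called genes of other-cell lists in the DN3 sets. No called result changed direction under the alternatives run; the DN3-low mean, not called, changed sign, between −0.02 and 0.01 log2 units without 1 library and 0.03 with the replicate block. Genes higher and lower in ZsGreen-positive ILC2 (323 and 300) numbered 621 and 460 without a filter, 168 and 64 with a fold limit of 1 log2 unit, 145 and 153 in the 2024 batch alone, 17 and 48 with the structural score and 29 and 31 with ZsGreen-positive library 1 alone, assumed to vary like the other group; genes higher numbered 211 under the stricter filter. Without 1 library at a time the ranges were 146 to 471 and 140 to 343, with 146 and 140 without ZsGreen-negative library 5, 149 and 172 without ZsGreen-positive library 2 and 148 and 154 without ZsGreen-positive library 3. Without ZsGreen-negative library 5 or ZsGreen-positive library 3 a lone 2025 library is absorbed by the batch term, so fewer libraries inform the test. The replicate number as a block gave 130 and 103 in place of batch, and 82 genes lower beside batch. Same-numbered libraries did not deviate together (r = 0.0728, −0.0897 and −0.0254 for numbers 1, 2 and 3 of the lung groups). Not every library correlated best with its own number, so the number does not pair samples. ZsGreen-negative library 3 with ZsGreen-positive library 2 (r = 0.153) and ZsGreen-negative library 2 with ZsGreen-positive library 1 (0.119) lay higher. In the 2025 batch, ZsGreen-negative library 5 with ZsGreen-positive library 3 had r = 0.134. The order of the library names places ZsGreen-negative libraries 1 and 2 beside ZsGreen-positive library 1. It places ZsGreen-negative libraries 3 and 4 beside ZsGreen-positive library 2, and ZsGreen-negative library 5 beside ZsGreen-positive library 3. The higher correlations just named fall within these sets, which may share a preparation. No block on such sets or pairs was run, so this pairing of the samples stays open. Lists called higher (7) numbered 1 with an estimated correlation, 1 with fry, 4 in the 2024 batch, 3 with the structural score and 2 to 11 without 1 library (3 without ZsGreen-negative library 2, 4 without 5, and 11, 2 and 4 without ZsGreen-positive libraries 1, 2 and 3). Lists called lower (1) numbered 0 with an estimated correlation and with fry, 3 without a filter, 2 without batch, 4 in the 2024 batch, 2 with block and batch and 1 to 4 without 1 library (2, 2 and 4 without ZsGreen-negative libraries 1, 3 and 5, and 2 and 4 without ZsGreen-positive libraries 1 and 3). Against DN3 a fold limit gave 3060 genes higher for ZsGreen-negative, 3112 for ZsGreen-positive and 3099 for all lung ILC2, with 4208 lower for the last; lists called higher (8) numbered 3 with an estimated correlation, and lists called lower (10) numbered 6 with it and 17 with fry. Leaving out 1 library kept every DN3 count within 1.5 times, with 5220 to 5901 genes higher and 6174 to 6541 lower than in all lung ILC2. The mean of the DN3-high set was 0.34 with 50 genes, 0.0043 with 500, 0.04 with block and batch, 0.05 with the structural score and 0.03 to 0.13 without 1 library, and the axis difference (0.0535) was 0.126 with 50 genes (exact permutation p = 0.0536), 0.0301 with 500 genes, 0.0822 and 0.0232 with pseudocounts of 0.1 and 5, 0.0472 over pairs in the block and 0.0131 to 0.0963 without 1 library. Of 1552 values of 68 called lung genes 282 lost the call, 45 of them with ZsGreen-positive library 1 alone, 40 with the structural score, 28 and 30 with the block in place of and beside batch and 22 or fewer in any other setting, and of 2418 values of 128 called DN3 genes 0 did (edgeR or the tool named). Fold limits and filters change counts by construction; for the other alternatives the cause was not tested. In the lung simulation, with 1 dispersion of 0.02 for every gene, changes of 0.5 log2 units were mostly missed, with 16.7% recovered. The share in the real libraries may differ.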

Other observations

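The list tests of this part were planned; the test of a different group effect in the 2 lung batches, the tests with the structural score and the look at Xist and Ddx3y were chosen after the data were seen.

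Single members of several lists differed between the lung groups, in both directions, while the lists themselves were not called. Of 30 immediate early genes 2 rose and 4 fell in ZsGreen-positive ILC2, against 3 and 6 adjusted over the list alone (camera, BH-adjusted p = 0.104), with the transcription factor gene Klf4 falling from 675 ± 45.5 to 427 ± 61.4 CPM. Of 20 neuro-immune receptors and lipid mediator genes 1 rose and 3 fell, against 3 and 5 adjusted over the list alone (camera, BH-adjusted p = 0.383). Of 23 glycolysis and hypoxia genes 0 rose and 2 fell, the same adjusted over the list alone (camera, BH-adjusted p = 0.159), with the hypoxia factor Hif1a at 337 ± 46.1 and 242 ± 23.3 CPM; the list median of 0.000677 log2 units turned negative under median-ratio scaling. Of 14 ILC3 and type 17 genes 1 rose and 3 fell, against 3 and 6 adjusted over the list alone (camera, BH-adjusted p = 0.333), with Scart1 rising and the cytokine gene Il17f falling from 16.3 ± 4.03 to 7.82 ± 1.43 CPM. The Il17f call was lost without ZsGreen-positive library 1 (edgeR BH-adjusted p = 0.0833), as was that of Hif1a (0.0901), and over 23 alternatives the adjusted p ranged from 2.73e-05 to 0.0904 and from 0.000152 to 0.404. With the structural score as a term Klf4 was no longer called, with a log2 fold change of −0.62 ± 0.15 (SE) against −0.66 ± 0.10 without it, while Hif1a and Il17f were. Structural markers, with a median 1.33 log2 units higher, moved with the same libraries.

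The remaining lists were not called between the lung groups either (camera, BH-adjusted p = 0.0747 or higher). Genes that rose and fell numbered 5 and 2 of 23 co-stimulatory receptors (6 and 2 adjusted over the list alone), 1 and 2 of 22 tissue residency genes (1 and 2), 1 and 1 of 17 ILC progenitor genes (3 and 3), 1 and 0 of 30 cytokine receptors (1 and 0), 1 and 0 of 5 ILC1, NK and cytotoxic genes (1 and 0), 1 and 1 of 11 fetal and imprinted genes (4 and 3), 1 and 2 of 23 lipid storage genes (3 and 3), 0 and 1 of 6 neutrophil and mast cell genes (2 and 1) and 1 and 0 of 85 ribosomal protein genes (1 and 0). The tissue retention receptor gene Cxcr4 fell from 205 ± 22.7 to 130 ± 8.49 CPM, and the IL-10 receptor gene Il10ra rose from 299 ± 19.4 to 400 ± 17.02 CPM, and neither was called with the structural score as a term. Their log2 fold changes were then −0.63 ± 0.15 (SE) for Cxcr4 and 0.36 ± 0.13 for Il10ra, against −0.64 ± 0.09 and 0.40 ± 0.08 without it. Of 40 cell cycle genes edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom; of 27 interferon response genes it called 0, with 3 at an unadjusted p under 0.05 and 0 by the other tools. Of 2 tested erythroid and platelet genes, too few for a list test, it called 0, with 1 at an unadjusted p under 0.05 and 0 by the other tools. Counts adjusted over the list alone were 0 for the first 2 of these lists and 1 for the last. Genes called by edgeR, DESeq2 and limma voom numbered 2, 3 and 4 in the fetal list, 1, 1 and 2 in the early thymic progenitor list and in the neutrophil and mast cell list, 1, 2 and 1 among cytokine receptors and 1, 1 and 0 among B cell markers. Median, mean and camera direction differed in sign for the Notch, fetal and residency lists (positive median and mean, direction down), the glycolysis list (positive median, mean and direction down), the ILC3 list (positive mean, median and direction down) and the interferon list (negative mean, median and direction up).

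In DN3 against all lung ILC2, fetal and imprinted genes were called higher (camera, BH-adjusted p = 0.00182), lost at an adjusted p = 0.222 with an estimated correlation, although 5 of 13 were higher and 8 lower and their median was −1.07 and mean −0.59 log2 units. H19, an imprinted fetal RNA, reached 451 ± 37.5 CPM in DN3. The other lists were not called (camera, BH-adjusted p = 0.136 or higher), with genes higher and lower numbering 4 and 6 of 12 early thymic progenitor genes, 3 and 3 of 6 ILC1, NK and cytotoxic genes, 14 and 9 of 34 interferon response genes, 2 and 7 of 11 MHC class II genes, 13 and 9 of 23 lipid storage genes, 7 and 13 of 24 glycolysis genes, 2 and 5 of 7 B cell genes, 2 and 12 of 15 macrophage genes, 0 and 6 of 6 neutrophil and mast cell genes, 2 and 4 of 13 mitochondrial transcripts and 5 and 61 of 86 ribosomal protein genes. Adjusted over the list alone these counts were the same except for macrophage genes (2 and 13) and mitochondrial transcripts (0 and 3). Both tested erythroid and platelet genes were lower. The ILC1, NK and cytotoxic list had a negative median and mean with direction up, and the lipid storage list a negative mean with median and direction up.

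On the lung libraries alone, the first principal component held 53.3% of the variance and ran from −17.7 in ZsGreen-negative library 4 to 22.7 in ZsGreen-positive library 3, with ZsGreen-negative library 3 (3.02) nearest to the ZsGreen-positive libraries (9.10 or more). It is also the ZsGreen-negative library with the highest structural score, at 4.15. On all 11 libraries the first component held 97.3% and separated DN3 from lung. A different group effect in the 2 lung batches was called by edgeR for 0 of 13771 genes, with 864 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma voom.

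Every lung library held both the female-specific transcript Xist (408 to 1072 CPM) and the Y-linked transcript Ddx3y (76.2 to 236 CPM). Among DN3 libraries, library 1 had Ddx3y at 99.9 CPM and Xist at 0.420 CPM, whereas libraries 2 and 3 had Xist at 2606 and 2605 CPM and Ddx3y at 0.634 and 0 CPM. DN3 library 1 therefore came from other animals than DN3 libraries 2 and 3. Each lung library held transcripts of both sexes, and sex was not a term in any fit.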
